A study of Mus musculus with 44 samples.

How the data were processed

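The count table holds 44 RNA-seq libraries of cultured primary mouse astrocytes and microglia. Per the labels, cells were purified from APOE33, APOE44, Apoe knock-out and wild-type mice and grown in media made for human cells without treatment, RNA was extracted with an RNeasy kit, and libraries were made with an NEBNext Ultra kit and sequenced as 150-base read pairs on a HiSeq instrument. The labels describe a single extraction batch, while a batch tag divides the libraries into batch 1 (32 libraries) and batch 2 (the 12 wild-type libraries). The table deposited by the authors holds raw counts per gene, with no normalization, and the submitters' processing notes name STAR 2.5.3a for alignment, featureCounts for counting and edgeR 3.26.8. The only build the notes name is a human one, hg38, although the 54146 gene identifiers are mouse Ensembl identifiers; the mouse build and annotation used by the authors are not given in the sources used here. Of these identifiers, 54079 matched GENCODE M21 by stable identifier and 52480 (96.9%) had the same version, so symbols and GRCm38 positions were taken from that release and 67 unmatched identifiers kept no symbol. The values are whole numbers that sum to 83239599 to 143150569 per library. Among counts from 1 to 9, 62.4% to 78.7% are even, as when both reads of a pair are counted, so a count is not a count of independent molecules. Of 102 pairs of libraries within a group none was identical, and the lowest chi-square per gene between replicates was 12.1.

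Samples were grouped by cell type and genotype from their titles. Astrocyte APOE33 replicate 1 carries a genotype tag of WT but is named APOE33 in its title and source and is tagged batch 1; it was kept in APOE33. For each cell type, APOE44 against APOE33 and knock-out against APOE33 were tested in the 16 libraries of batch 1, and knock-out and APOE33 against wild type in all 22 libraries. The difference of the genotype effects between the cell types, and microglia against astrocytes averaged over 3 genotypes, were tested in the 32 libraries of batch 1. Tests were run in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr on the groups, libraries were scaled by TMM, and robust quasi-likelihood F tests were fitted with sex as a covariate (within cell type for the joint fit). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Every adjusted p of a gene is from this edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and a standard error is the log2 fold change divided by the square root of the F statistic. Log2 values come from the fitted model, and levels are counts scaled to a common library total (CPM).

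The comparisons, covariates, alternatives, 26 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover cholesterol biosynthesis enzymes, sterol uptake and SREBP regulators, LXR targets and cholesterol efflux, fatty acid synthesis and lipid droplets, lysosome and intracellular cholesterol trafficking, collagens and matrix glycoproteins, matrix proteoglycans, matrix regulators, chemokines with cytokines and growth factors, type I interferon response, antigen presentation, disease-associated microglia genes, homeostatic microglia genes, reactive astrocyte genes, complement and phagocytosis, cell cycle and the neighbours of Apoe on chromosome 7. The other lists hold markers of astrocytes, microglia and macrophages, border macrophages and monocytes, the oligodendrocyte lineage, neurons, endothelium, mural cells and meningeal fibroblasts, ependyma and choroid, and erythrocytes; the erythrocyte list had fewer than 2 measured members and was not tested. Lists share members (Spp1, the cathepsins and C3, for example), so their tests are not independent. Each list was tested with camera in limma 3.58.1 on log CPM (prior count 2) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 25 lists of a comparison. Camera with an estimated correlation and fry were run beside it; fry asks whether a list's genes move, on balance, 1 way, and does not compare the list with other genes. By camera, 91 of 275 list tests were called, and 2 of them also with an estimated correlation. Members called at an adjusted p within the list are given as adjusted over the list alone. Where all libraries of a group had no count of a member, its fold is only a bound; with such members set to the bound from a floor of 3 counts over the group, every list median stayed as printed.

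Named genes follow the fixed rule: Apoe; the called genes with the largest rises and falls (6 each against APOE33, 4 each against wild type) with a mean log CPM of at least 1 and a symbol other than a predicted-gene name, Xist, Tsix or a gene on chromosome Y; up to 4 called members of each list with the smallest adjusted p, or the 1 with the smallest where none was called; and the 8 genes with the smallest adjusted p of each interaction. The genes named among those called in both cell types, the fold of Mvd in knock-out astrocytes and of Ncapg2 in APOE44 astrocytes, and the levels of Sqle, Lrmda and Wdfy1 in the knock-out fall outside this rule and were chosen after their values were seen. Positions of called genes were compared with 1000 random sets of tested genes of the same size. Here and in later counts, another call nearby counted only where the first 4 letters of its symbol differed. Serpina3g and Serpina3m thus did not count for each other, while overlapping predicted genes could. Calls per chromosome and in windows around Apoe were compared with Fisher's exact test (two-sided, Benjamini-Hochberg adjusted). The correlation of the APOE44 and knock-out effects was set against 20 simulated pairs of unchanged groups that share simulated controls. It was also taken with the APOE33 libraries split into odd and even replicate numbers, so that the effects shared none.

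The tests were tried on simulated data with 200 genes changed among libraries drawn with the fitted means and dispersions, in 22 simulated datasets. Before the first run a level of 80% recovery of 4-fold changes was set. With changed genes drawn from those expressed over all libraries, 9 of 11 comparisons reached it (69.7% to 93.9%); with genes drawn from those expressed in the changed libraries, a rule chosen after the first run, 10 of 11 did (78.8% to 100%). The highest share of false calls was 7.32%. The simulated libraries held no structure of their own. Other splits of the real APOE33 and APOE44 libraries called up to 386 genes in astrocytes and 281 in microglia. The simulated share may therefore be too low for the real data. Under the second rule, APOE44 against APOE33 recovered 65.7% of 1.5-fold, 61.2% of 2-fold and 92.4% of 4-fold changes over 20481 genes in astrocytes, and 35.8%, 79.1% and 87.9% over 17143 genes in microglia, and the missed genes had higher dispersions than the called ones.

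Alternatives fixed with the design were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter, a stricter filter of 1 CPM in 4 libraries, no sex covariate, sex and RIN as covariates, the replicate number as a block, only the libraries of the compared groups, an absolute log2 fold change of at least 1 as well, each library left out in turn, and windows of 2 and 10 Mb around Apoe. Fits without the libraries highest in markers of other cell types, with the class of even low counts as a covariate, and without chromosomes 6, 7 and 12 were added after the data were seen. Splits of the libraries into other groups of the same sizes gave the number of genes called for unrelated groupings. Reads of human APOE were not used here.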

Results

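RNA was sequenced from primary mouse astrocytes and microglia grown in culture, with 22 libraries of each cell type. The cells came from mice of 4 genotypes: human APOE3 or APOE4 knocked in on both alleles (APOE33 and APOE44), no functional Apoe (knock-out), and unedited mouse Apoe (wild type). Each cell type had 6 wild-type, 6 APOE33, 6 APOE44 and 4 knock-out libraries, of both sexes. Knock-out replicate 1 is the only female knock-out library in each cell type, beside 3 males, and APOE33 has 4 females and 2 males. All 12 wild-type libraries are tagged as batch 2 and the other 32 libraries as batch 1. Genotype and batch therefore cannot be told apart in any comparison with wild type. Total counts per library ran from 83239599 to 143150569 in astrocytes and from 86313947 to 120505499 in microglia, and RIN from 8.9 to 10. The labels do not say whether replicates are separate animals or separate cultures, so every p value measures only the spread between these libraries.

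Apoe (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188 on GRCm38) encodes the lipid carrier apolipoprotein E. It stood at 7190 ± 632 CPM (SD, n = 6) in wild-type astrocytes and at 43200 ± 4160 CPM (SD, n = 6) in wild-type microglia. In the knock-out it stood at 13.3 ± 1.75 CPM (SD, n = 4) in astrocytes and 12.4 ± 7.34 CPM (SD, n = 4) in microglia. Against wild type, Apoe fell by 9.08 on the log2 scale in knock-out astrocytes (SE 0.20, edgeR adjusted p = 1.15e-18). In knock-out microglia it fell by 11.70 (SE 0.42, edgeR adjusted p = 3.6e-13). Human APOE has no entry of its own in the mouse count table, so the knock-in values count only reads assigned to the mouse gene. These were 28.4 ± 5.19 CPM in APOE33 and 29.1 ± 5.03 CPM in APOE44 astrocytes, and 46.7 ± 10.9 and 45.8 ± 3.52 CPM in the microglia (SD, n = 6 each). Apoe was lower in knock-out than in APOE33 cells by a log2 value of -1.21 in astrocytes (SE 0.15, adjusted p = 0.000245) and -1.85 in microglia (SE 0.32, adjusted p = 0.00111). Between APOE44 and APOE33 no difference was detected, at -0.0039 in astrocytes (SE 0.12, adjusted p = 0.997) and -0.04 in microglia (SE 0.26, adjusted p = 0.97). Astrocyte APOE33 replicate 1, whose genotype tag reads WT while its title and source name read APOE33, had Apoe at 24.4 CPM. Xist and the Y-linked genes went with the sex label in 44 of 44 libraries.

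**Figure D1:**
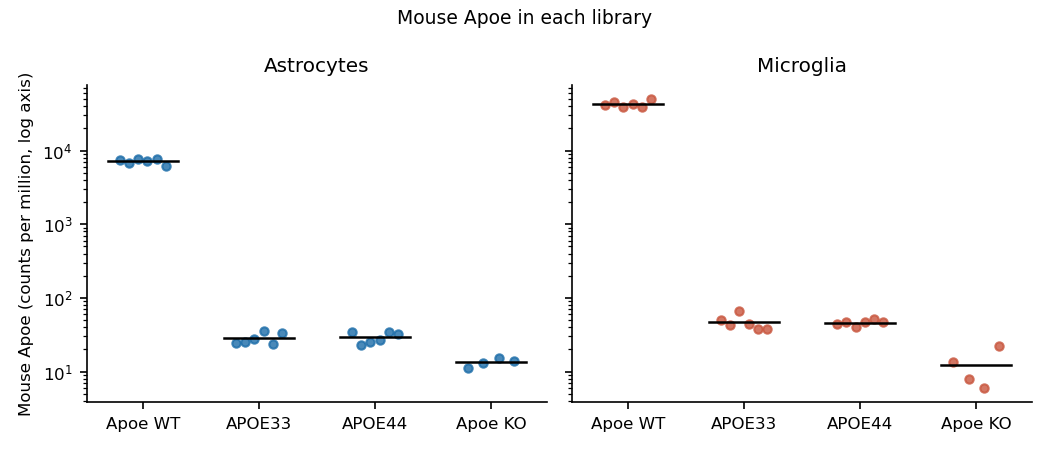
Mouse Apoe level in CPM on a log axis for each of the 44 libraries, by genotype and cell type, with points for libraries and lines for group means. Wild-type libraries average 7190 CPM in astrocytes and 43200 CPM in microglia, and those of the other genotypes lie between 5.99 and 66.7 CPM.

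Microglia and astrocytes of batch 1 carried the transcripts of their own lineages. All 18 measured microglia and macrophage markers were higher in microglia, with a median log2 difference of 6.82 (camera adjusted p = 2.21e-08; adjusted p = 0.233 with an estimated correlation). Aif1, a calcium-binding protein of microglia, was higher by 8.07 (SE 0.22, n = 16 and 16 libraries, adjusted p = 1.7e-22). Of 18 astrocyte markers, 17 were lower in microglia, with a median of -7.35 (camera adjusted p = 2.09e-05; adjusted p = 0.208 with an estimated correlation). Among them were the intermediate filament gene Gfap at -8.33 (SE 0.28, adjusted p = 1.45e-20) and the growth factor receptor gene Fgfr3 at -8.54 (SE 0.14, adjusted p = 6.4e-28). Microglia had higher levels of 28 of 29 lysosomal genes (median 2.30, camera adjusted p = 5.79e-11). The same held for 26 of 28 disease-associated microglia genes (median 5.74, camera adjusted p = 3.36e-09). Both lists had adjusted p = 0.0944 with an estimated correlation. Of 63 collagens and matrix glycoproteins, 56 were lower and 5 higher in microglia, with a median of -5.10 (camera adjusted p = 8.55e-07; adjusted p = 0.208 with an estimated correlation). In APOE33 cells, the microglia markers had a median level of 1298 ± 101 CPM in microglia against 12.4 ± 5.92 CPM in astrocytes (SD, n = 6 each). The astrocyte markers stood at 434 ± 20.3 CPM in astrocytes against 1.24 ± 1.16 CPM in microglia (SD, n = 6 each). In all, 18643 of 21647 genes differed, 8175 higher and 10468 lower in microglia (edgeR), around a median of -0.26 over all genes.

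Comparing APOE44 with APOE33, the question named by the series title for human cells, was possible inside batch 1 with 6 libraries per group. In astrocytes, Wdfy1 (ENSMUSG00000073643.11, chromosome 1, 79702262 to 79776143), which encodes a phosphoinositide-binding protein of endosomes, fell by 2.29 on the log2 scale (SE 0.040, adjusted p = 7.47e-16). Its level was 73.8 ± 3.62 CPM in APOE33 and 15.0 ± 0.909 CPM in APOE44 (SD, n = 6 each). Eps8l1 (ENSMUSG00000006154.13, chromosome 7, 4460674 to 4480487), a relative of the actin regulator Eps8, rose by 4.09 (SE 0.17, adjusted p = 1.85e-10), from 0.699 ± 0.0456 to 11.7 ± 1.65 CPM (SD, n = 6 each). The serine protease inhibitor genes Serpina3g and Serpina3m, neighbours on chromosome 12, rose by 5.14 (SE 0.62, adjusted p = 0.000703) and 3.99 (SE 0.63, adjusted p = 0.00735). Ptprn2, a receptor-type phosphatase gene, rose by 1.73 (SE 0.11, adjusted p = 2.78e-07). Cttnbp2, a cortactin-binding protein, fell by 1.11 (SE 0.043, adjusted p = 8.79e-11) and the pro-apoptotic gene Bid fell by 1.05 (SE 0.084, adjusted p = 1.09e-06). Vldlr, a lipoprotein receptor, rose by 0.585 (SE 0.095, adjusted p = 0.00443), the only 1 of 13 sterol uptake and SREBP regulators to pass. In all, 144 of 20481 genes changed, 86 up and 58 down (edgeR), against 2029 at an unadjusted p under 0.05. Leaving out 1 library left 95 changed genes without APOE33 replicate 3, and 88, 85 and 87 without APOE44 replicates 4, 5 and 6.

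Among the 20 cholesterol biosynthesis enzymes in the same astrocytes, 20 of 20 log2 values were negative, with a median of -0.16. Over all genes tested 1 fell, Cyp51 (-0.25, SE 0.053, adjusted p = 0.0418), and 10 fell when adjusted over the list alone (camera adjusted p = 4.64e-10; adjusted p = 0.596 with an estimated correlation). No astrocyte marker passed over all genes and 3 of 18 rose adjusted over the list alone (median 0.05, camera adjusted p = 0.0111). None of 34 cell cycle genes passed (median -0.15, camera adjusted p = 0.0096). Both lists had adjusted p = 0.972 with an estimated correlation. At an unadjusted p under 0.05 they had 3 and 0 genes, and DESeq2 called 3 and 0. Of the 62 collagens and matrix glycoproteins 0 passed (edgeR; 11 at an unadjusted p under 0.05, 3 by DESeq2; camera adjusted p = 0.93). In the matrix proteoglycans, Omd, a keratan sulfate proteoglycan of bone, fell (-0.47, SE 0.094, adjusted p = 0.032). The 22 lists other than the enzymes, astrocyte markers and cell cycle genes had a camera adjusted p of 0.0695 or more. The cell cycle call was lost without APOE33 replicate 1 or 2 or APOE44 replicate 4 (camera adjusted p = 0.0536, 0.145 and 0.0729). The astrocyte marker call was lost without APOE33 replicate 2 or 5 or APOE44 replicate 6 (camera adjusted p = 0.057, 0.116 and 0.0561). Cyp51 lost its call without any 1 of these libraries other than APOE33 replicate 6 (adjusted p from 0.0543 to 0.123). Omd lost it without APOE33 replicate 2, 3, 4, 5 or 6 or APOE44 replicate 1, 4, 5 or 6 (adjusted p from 0.0537 to 0.0942).

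In APOE44 microglia, Eps8l1 rose as well, by 7.78 (SE 0.31, adjusted p = 3.3e-10), from 0.0441 ± 0.0223 to 9.29 ± 2.72 CPM (SD, n = 6 each). Lrmda, a gene of melanocyte differentiation, rose by 3.16 (SE 0.091, adjusted p = 1.26e-12) and Plxnd1, a semaphorin receptor, by 1.87 (SE 0.058, adjusted p = 3.07e-12). Pirb, an inhibitory receptor for MHC class I, rose by 1.44 (SE 0.24, adjusted p = 0.00882). Ncapg2, a condensin subunit, fell by 2.65 (SE 0.074, adjusted p = 1.08e-12), from 60.7 ± 3.43 to 9.67 ± 1.25 CPM (SD, n = 6 each). Wdfy1 fell by 1.94 (SE 0.045, adjusted p = 1.21e-13) and Bid by 0.82 (SE 0.057, adjusted p = 3.71e-07). Of 39 measured neighbours of Apoe, the transcriptional repressor gene Irf2bp1 and the ubiquitin ligase gene Fbxo46 fell (-0.26, SE 0.048, adjusted p = 0.0128; -0.36, SE 0.078, adjusted p = 0.0388). The list had a median of -0.08 (camera adjusted p = 0.00606; adjusted p = 0.594 with an estimated correlation), and its call was lost without APOE33 replicate 3 (camera adjusted p = 0.0794). Irf2bp1 lost its call without APOE44 replicate 4 (adjusted p = 0.0558). Fbxo46 lost it without any 1 of these libraries other than APOE33 replicates 1 and 2 and APOE44 replicate 5 (adjusted p from 0.0691 to 0.112). In all, 144 of 17143 genes changed, 65 up and 79 down (edgeR), against 2037 at an unadjusted p under 0.05. Leaving out 1 library left 95 without APOE33 replicate 4, and 90 and 81 without APOE44 replicates 1 and 4.

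No member of the type I interferon response list passed in APOE44 microglia, but 36 of 36 log2 values were positive with a median of 0.66 (camera adjusted p = 1.59e-11; adjusted p = 0.594 with an estimated correlation). Of these genes, 19 had an unadjusted p under 0.05 and DESeq2 called 5. Their median level stood apart in APOE44 replicates 1, 3 and 6, at 29.1, 26.3 and 31.1 CPM. APOE44 replicates 2, 4 and 5, at 16.7, 14.3 and 9.39 CPM, lay within the APOE33 range of 5.8 to 18.5 CPM. In the same libraries, 16 of 16 oligodendrocyte lineage markers were positive with a median of 1.06 (camera adjusted p = 3.35e-07; adjusted p = 0.594 with an estimated correlation). None of them passed, 3 had an unadjusted p under 0.05 and DESeq2 called 0. Their level was 0.286 ± 0.355 CPM in APOE33 and 0.739 ± 0.475 CPM in APOE44 (SD, n = 6 each). Also with no member passing, the collagens and matrix glycoproteins had a median of 0.34 over 53 genes (camera adjusted p = 0.00417; adjusted p = 0.773 with an estimated correlation). The reactive astrocyte genes had 0.29 over 31 (camera adjusted p = 0.00417; adjusted p = 0.594 with an estimated correlation). Beside them, astrocyte markers had 0.52 over 15 (camera adjusted p = 0.0115; adjusted p = 0.795 with an estimated correlation) and neuron markers 0.70 over 9 (camera adjusted p = 0.014; adjusted p = 0.594 with an estimated correlation). At an unadjusted p under 0.05 these 4 lists had 4, 2, 0 and 0 genes, and DESeq2 called 1 reactive astrocyte gene. The astrocyte marker call was lost without APOE33 replicate 1 or 3 or APOE44 replicate 3 or 6 (camera adjusted p = 0.0613, 0.0794, 0.0701 and 0.102). That of the neuron markers was lost without APOE33 replicate 1 or APOE44 replicate 3 or 6 (camera adjusted p = 0.0604, 0.0701 and 0.0749). No cholesterol biosynthesis enzyme passed, with a median of -0.03 over 20, 0 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.937). The other 17 lists were not called.

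The APOE44 calls lay in groups along the chromosomes. Of the 144 astrocyte calls, 71 (49.3%) had another call within 1 Mb, against 25.7% at the 95th percentile and 33.3% at the highest of 1000 random sets of tested genes. In microglia it was 54 of 136 outside the mitochondrial genome (39.7%), against 26.5% and 32.4%. Chromosome 6 held 37 astrocyte calls, 3.43% of its tested genes against 0.553% elsewhere (Fisher's exact test, adjusted p = 8.15e-15), and 23 microglia calls (adjusted p = 1.02e-05). Chromosome 7 held 29 microglia calls (adjusted p = 1.02e-05) and 19 astrocyte calls, which did not pass (adjusted p = 0.116). Chromosome 12 held 13 astrocyte calls (adjusted p = 0.0272) and 7 microglia calls, which did not pass (adjusted p = 0.633). Fewer calls than elsewhere lay on chromosome 11 in astrocytes (2 of 1516 genes, adjusted p = 0.021) and chromosome 8 in microglia (0 of 926, adjusted p = 0.00595). Neither passed in the other cell type (adjusted p = 0.651 and 0.232). Within 5 Mb of Apoe, none of 125 genes changed in astrocytes (edgeR; 12 at an unadjusted p under 0.05 and 1 by DESeq2) and 3 of 111 in microglia (Fisher's exact test, adjusted p = 1 and 0.0787). Between 5 and 20 Mb away on chromosome 7, 15 of 415 (3.61%) and 20 of 362 (5.52%) changed, against 0.647% and 0.726% of other genes (adjusted p = 1.06e-06 and 1.56e-10). Of 16067 genes tested in both cell types, 27 were called in both, 13 up and 14 down, against 0.896 expected of independent lists. Every one went in the same direction. They include Wdfy1, Eps8l1, Bid, Plxnd1 and both Serpina3 genes, and 7 lie on chromosome 6, 7 on chromosome 7, 4 on chromosome 17 and 3 on chromosome 12.

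**Figure D2:**
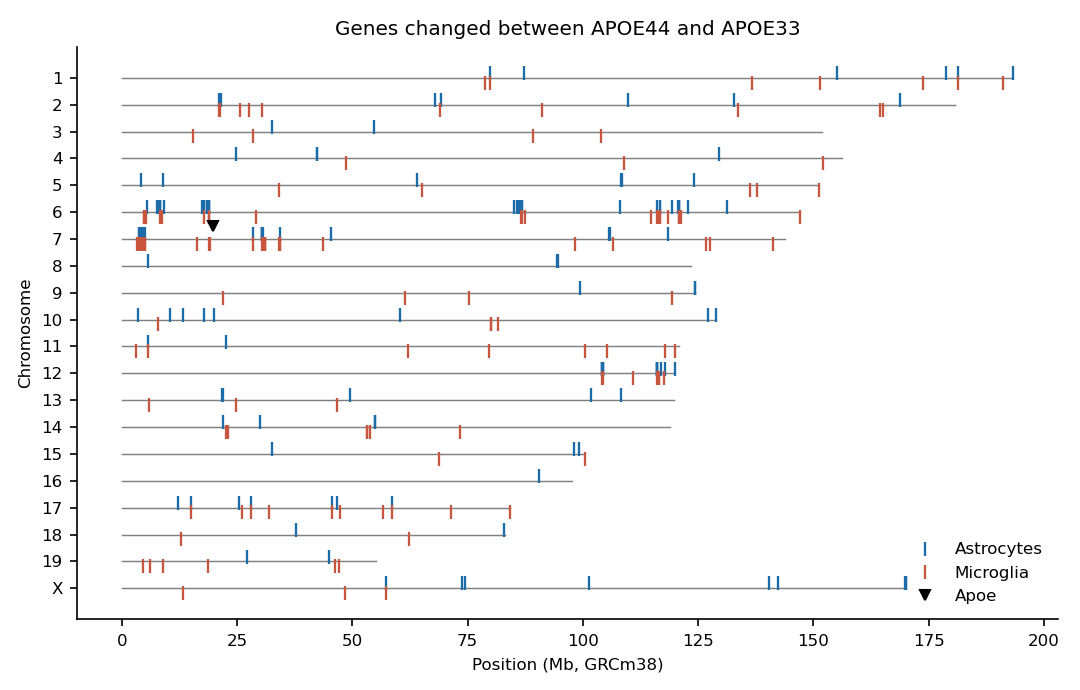
Position in Mb (horizontal axis, GRCm38) along each chromosome (vertical axis) of the genes changed in APOE44 against APOE33, with each mark a gene coloured by cell type and a triangle at Apoe. The marks bunch on chromosome 6 (37 in astrocytes, 23 in microglia) and chromosome 7 (29 in microglia).

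Comparing the knock-out with APOE33 sets the absence of apolipoprotein E against the human APOE3 protein inside batch 1, with 4 knock-out and 6 APOE33 libraries per cell type. In astrocytes, 12 of 20 cholesterol biosynthesis enzymes fell, 0 rose and 8 did not pass, and 16 fell adjusted over the list alone. Their median log2 value was -0.36 (camera adjusted p = 1.32e-10; adjusted p = 0.524 with an estimated correlation). Hmgcs1, the HMG-CoA synthase, fell by 0.66 (SE 0.081, adjusted p = 0.000186), from 150 ± 7.65 CPM (SD, n = 6) to 97.9 ± 13.2 CPM (SD, n = 4). The squalene epoxidase gene Sqle fell by 0.56 (SE 0.061, adjusted p = 5.76e-05). Srebf2, the transcriptional activator of these enzymes, fell by 0.29 (SE 0.060, adjusted p = 0.00437). Of 13 sterol uptake and SREBP regulators, 2 rose and 4 fell (camera adjusted p = 0.768). Of 29 lysosomal genes 7 rose and 0 fell, with a median of 0.11 (camera adjusted p = 0.034; adjusted p = 0.534 with an estimated correlation). Among them, the lysosomal lipase gene Lipa rose by 0.32 (SE 0.048, adjusted p = 0.000675). The immediate early genes Egr1 and Fos fell by 3.48 (SE 0.61, adjusted p = 0.0028) and 3.24 (SE 0.58, adjusted p = 0.00307). Egr1 varied from 36.6 to 282 CPM among APOE33 astrocytes and from 8.65 to 11.3 among the knock-out. Eps8l1, low in APOE33 alone, rose by 3.42 (SE 0.18, adjusted p = 1.26e-08). Without knock-out replicate 1, 2 sterol regulators fell and 0 rose, and 3 lysosomal genes rose. Without APOE33 replicate 3, 2 lysosomal genes rose. The lysosomal list lost its call there and without knock-out replicate 2 (camera adjusted p = 0.14 and 0.066).

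In the same knock-out astrocytes, 9 of 28 disease-associated microglia genes rose and 2 fell (median 0.31, camera adjusted p = 0.0093; adjusted p = 0.534 with an estimated correlation). The secreted phosphoprotein gene Spp1 rose by 1.34 (SE 0.28, adjusted p = 0.00637) and the lysozyme gene Lyz2 by 1.2 (SE 0.26, adjusted p = 0.00834). Of 29 complement and phagocytosis genes, 6 rose and 0 fell (median 0.52, camera adjusted p = 0.00862; adjusted p = 0.534 with an estimated correlation). Beside them, microglia and macrophage markers had 18 of 18 positive values and a median of 0.76, with 1 passing, Aif1 (camera adjusted p = 0.00194; adjusted p = 0.804 with an estimated correlation). Their level was 18.8 ± 5.98 CPM (SD, n = 4) against 12.4 ± 5.92 CPM (SD, n = 6) in APOE33. Of 9 border macrophage markers 3 rose (median 1.07, camera adjusted p = 0.0093; adjusted p = 0.534 with an estimated correlation). Of 35 reactive astrocyte genes, 6 rose and 2 fell, and the list was not called (camera adjusted p = 0.768). Among these, the asparaginase gene Aspg rose by 1.74 (SE 0.23, adjusted p = 0.000245) and Cp, the ceruloplasmin gene, by 1.2 (SE 0.21, adjusted p = 0.00237). Of 62 collagens and matrix glycoproteins, 8 rose, such as the fibulin gene Efemp1 (1.06, SE 0.15, adjusted p = 0.000715), and 11 fell, such as the laminin gene Lama2 (-0.67, SE 0.11, adjusted p = 0.000991). That list was not called (camera adjusted p = 0.231). Oligodendrocyte lineage markers fell in 8 of 17 (median -1.09, camera adjusted p = 0.00194) and ependymal and choroid markers in 5 of 10 (median -1.22, camera adjusted p = 0.000419). Both had adjusted p = 0.534 with an estimated correlation. In all, 3522 of 20481 genes changed, 1714 up and 1808 down (edgeR), or 2347 without APOE33 replicate 3 and 1836 without knock-out replicate 1.

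Single libraries moved several of these astrocyte counts. Knock-out replicate 1 lies at a chi-square per gene of 87.26 to 130.3 from the other knock-out libraries, which lie at 18.22 to 45.02 from each other. It is also the only female of the group, so sex and other traits of this library cannot be told apart within the knock-out. Without APOE33 replicate 3, 3 disease-associated, 3 complement, 3 reactive and 0 microglia marker genes rose and 3 oligodendrocyte markers fell. Without knock-out replicate 1, 4 disease-associated and 3 reactive genes rose. In that case, 6 collagens and glycoproteins, 2 oligodendrocyte markers and 3 ependymal markers fell. Without knock-out replicate 3, 3 complement and 3 reactive genes rose and 5 oligodendrocyte markers fell. Without knock-out replicate 4, 5 disease-associated genes rose and 4 oligodendrocyte markers fell. Without APOE33 replicate 2, 6 microglia markers rose. Aif1 lost its call without APOE33 replicate 1, 3, 4, 5 or 6 or knock-out replicate 1, 2 or 4 (adjusted p from 0.0508 to 0.138).

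In microglia the same comparison gave the opposite change in sterol genes. All 20 cholesterol biosynthesis enzymes rose in the knock-out, with a median of 1.5 (camera adjusted p = 1.63e-17; adjusted p = 0.186 with an estimated correlation). Their median level was 14.7, 19.5 and 17.3 CPM in APOE33 replicates 1, 2 and 3 and 25.2, 31.2 and 22.8 CPM in replicates 4, 5 and 6. In the knock-out it was 48.8 to 58.5 CPM, so the size of the rise, though not its direction, depends on the APOE33 libraries taken. Lss, the lanosterol synthase, rose by 1.72 (SE 0.18, adjusted p = 2.99e-05) and Mvd, a mevalonate pathway decarboxylase, by 1.51 (SE 0.17, adjusted p = 3.26e-05). Tm7sf2, a sterol reductase, rose by 1.23 (SE 0.11, adjusted p = 5.6e-06). Sqle stood at 31.4 ± 17.5 CPM in APOE33 (SD, n = 6) and 99.5 ± 11.1 CPM in the knock-out (SD, n = 4). Insig1, a sterol sensor of the SREBP system, rose by 1.45 (SE 0.17, adjusted p = 4.77e-05) and Srebf2 by 0.62 (SE 0.11, adjusted p = 0.00109). Of 13 sterol uptake and SREBP regulators, 6 rose and 1 fell (median 0.34, camera adjusted p = 0.00309; adjusted p = 0.248 with an estimated correlation). Of 22 genes of fatty acid synthesis and lipid droplets, 11 rose and 1 fell (median 0.30, camera adjusted p = 0.000417; adjusted p = 0.171 with an estimated correlation). They include the desaturase gene Fads1 (0.76, SE 0.070, adjusted p = 4.44e-06) and the fatty acid binding protein gene Fabp5 (1.28, SE 0.18, adjusted p = 0.000196). Of 15 LXR targets and efflux genes, 4 rose and 3 fell, and the list was not called (camera adjusted p = 0.785). Nr1h3, the gene of LXR alpha, rose by 1.67 (SE 0.21, adjusted p = 0.000101) and the cholesterol 25-hydroxylase gene Ch25h fell by 1.22 (SE 0.15, adjusted p = 9.8e-05). Lysosomal genes rose in 14 of 29 and fell in 3 (median 0.20, camera adjusted p = 0.000763; adjusted p = 0.649 with an estimated correlation). Npc1, an exporter of lysosomal cholesterol, rose by 0.49 (SE 0.069, adjusted p = 0.000146). Without knock-out replicate 1, 8 lysosomal genes rose and the list was not called (camera adjusted p = 0.0662).

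**Figure D3:**
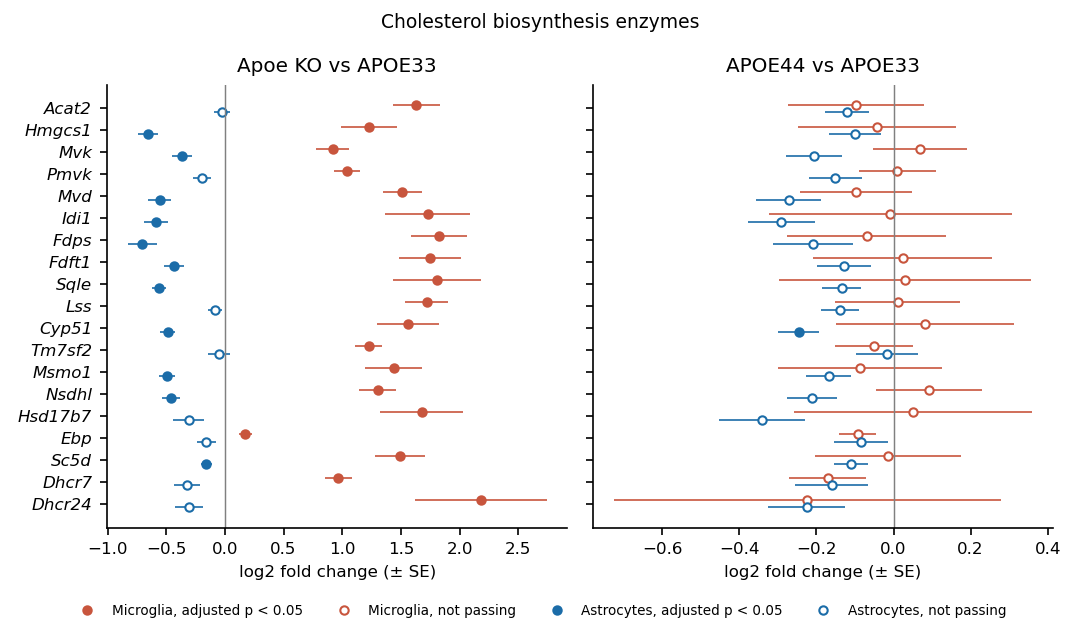
Log2 fold change (horizontal axis, bars ± SE) of 19 of the 20 cholesterol biosynthesis enzymes in knock-out and in APOE44 against APOE33, for microglia and astrocytes, with filled points at an adjusted p under 0.05. In the knock-out, the 20 enzymes have a median of 1.5 in microglia and -0.36 in astrocytes.

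Knock-out microglia also had lower levels of many homeostatic microglia genes and of some chemokines, cytokines and growth factors. Of 21 homeostatic microglia genes, 14 fell and 0 rose (median -0.58, camera adjusted p = 6.46e-07; adjusted p = 0.367 with an estimated correlation). Their median level was 442, 414 and 490 CPM in APOE33 replicates 1, 2 and 3, 252, 238 and 245 CPM in APOE33 replicates 4, 5 and 6, and 137 to 196 CPM in the knock-out, so the size of the fall depends on the APOE33 libraries taken. Tmem119, a membrane protein of microglia, fell by 1.74 (SE 0.15, adjusted p = 4.94e-06), from 422 ± 69.5 CPM (SD, n = 6) to 128 ± 30.9 CPM (SD, n = 4). Sall1, a transcription factor of microglial identity, fell by 2.42 (SE 0.35, adjusted p = 0.00032) and the purinergic receptor gene P2ry12 by 0.70 (SE 0.19, adjusted p = 0.0148). Without knock-out replicate 1, P2ry12 lost its call (adjusted p = 0.101). Of 39 chemokines, cytokines and growth factors, 14 fell and 2 rose (median -0.49, camera adjusted p = 0.000417; adjusted p = 0.171 with an estimated correlation). The chemokine genes Ccl2 and Cxcl2 fell by 2.40 (SE 0.34, adjusted p = 0.000197) and 2.79 (SE 0.52, adjusted p = 0.00179), and the prostaglandin synthase gene Ptgs2 by 3.16 (SE 0.34, adjusted p = 3.26e-05). Of 9 border macrophage and monocyte markers, 6 rose (median 1.02, camera adjusted p = 0.000907; adjusted p = 0.186 with an estimated correlation), such as the mannose receptor gene Mrc1 (1.44, SE 0.26, adjusted p = 0.0013). Of 18 microglia and macrophage markers, 5 fell and 1 rose (median -0.13, camera adjusted p = 0.0496; adjusted p = 0.764 with an estimated correlation). Their call was lost without APOE33 replicate 1 or 3 or knock-out replicate 2 or 3 (camera adjusted p = 0.0638, 0.288, 0.0507 and 0.0557). The scavenger receptor gene Marco rose by 2.82 (SE 0.42, adjusted p = 0.000356). Apoc4, the apolipoprotein gene beside Apoe, rose by 2.85 (SE 0.51, adjusted p = 0.00125), from 1.18 ± 0.751 CPM (SD, n = 6) to 8.40 ± 2.39 CPM (SD, n = 4). Of 39 neighbours of Apoe 6 rose and 7 fell, with the kinase gene Dmpk at -2.56 (SE 0.22, adjusted p = 2.74e-06). In all, 3899 of 17143 genes changed, 1863 up and 2036 down (edgeR).

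Disease-associated genes of the knock-out microglia went both ways, with 7 of 28 up and 4 down (camera adjusted p = 0.208). Gpnmb, a lysosomal glycoprotein, rose by 1.16 (SE 0.21, adjusted p = 0.00119) and the growth factor gene Csf1 fell by 0.88 (SE 0.17, adjusted p = 0.00172). Of 45 matrix regulators, 6 rose and 2 fell (camera adjusted p = 0.127), with Mmp14, a membrane-bound metalloproteinase gene, up by 1.24 (SE 0.14, adjusted p = 3.99e-05). Of 53 collagens and matrix glycoproteins, 8 rose and 3 fell (camera adjusted p = 0.115), and 5 rose without knock-out replicate 4. Of 14 matrix proteoglycans 0 passed (edgeR; 2 at an unadjusted p under 0.05 and 1 by DESeq2; camera adjusted p = 0.704). Complement and phagocytosis genes rose in 8 of 30 and fell in 5 (camera adjusted p = 0.118), with 5 up without knock-out replicate 1. Reactive astrocyte genes rose in 4 of 31 and fell in 5 (camera adjusted p = 0.347). Antigen presentation genes rose in 6 of 21 and fell in 1 (median 0.12, camera adjusted p = 0.0119; adjusted p = 0.649 with an estimated correlation). Their call was lost without APOE33 replicate 6 (camera adjusted p = 0.116). Cell cycle genes had 32 of 34 negative values with 1 up and 2 down (median -0.64, camera adjusted p = 0.00433; adjusted p = 0.764 with an estimated correlation), and lost their call without knock-out replicate 1 (camera adjusted p = 0.598). Of them 0 were up and 1 down without APOE33 replicate 3 or knock-out replicate 1 or 4, and 4 were down without knock-out replicate 2.

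Of 36 type I interferon genes 4 rose (camera adjusted p = 0.336), but 0 without knock-out replicate 1, 2 without APOE33 replicate 1 or 6, and 1 without APOE33 replicate 3 or knock-out replicate 2 or 3. Oligodendrocyte lineage markers fell in 8 of 16 (median -2.73, camera adjusted p = 0.00433; adjusted p = 0.649 with an estimated correlation). Their level was 0.286 ± 0.355 CPM in APOE33 (SD, n = 6) and 0.0272 ± 0.0128 CPM in the knock-out (SD, n = 4). Without knock-out replicate 1, 4 of them fell, and 5 without APOE33 replicate 3 or knock-out replicate 3. The marker lists of astrocytes, neurons, endothelium, mural cells with meningeal fibroblasts, and ependyma were not called (camera adjusted p from 0.197 to 0.977).

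Whether the knock-out effect differed between the cell types was tested as an interaction over the 32 libraries of batch 1, taken as independent. All 20 cholesterol biosynthesis enzymes had a higher knock-out effect in microglia than in astrocytes, with a median difference of 1.84 (camera adjusted p = 5.48e-33; adjusted p = 0.0206 with an estimated correlation). Mvd differed by 2.06 (SE 0.20, adjusted p = 4.71e-07), with -0.555 in astrocytes and 1.51 in microglia. Of 22 fatty acid and lipid droplet genes, 9 differed, all higher in microglia (median 0.39, camera adjusted p = 9.5e-06; adjusted p = 0.0206 with an estimated correlation). Over the 11 comparisons these are the only 2 list calls that held with an estimated correlation. Smpdl3a, an LXR target, differed by 1.26 (SE 0.13, adjusted p = 4.71e-07) and the glutathione transferase gene Mgst1 by 1.51 (SE 0.15, adjusted p = 4.71e-07). Both were lower in knock-out astrocytes and higher in knock-out microglia, but the astrocyte call of Smpdl3a was lost without astrocyte knock-out replicate 1 (-0.16, adjusted p = 0.0671). Dmpk differed by -3.26 (SE 0.26, adjusted p = 1.32e-08). Homeostatic microglia genes had a lower effect in microglia, with a median of -0.86 (camera adjusted p = 1.91e-05; adjusted p = 0.377 with an estimated correlation). Of them 6 of 21 passed, or 10 without astrocyte APOE33 replicate 2 or knock-out replicate 3. Chemokines, cytokines and growth factors had a median of -0.79, with 9 of 41 lower (camera adjusted p = 0.00121; adjusted p = 0.17 with an estimated correlation). Beside them, microglia and macrophage markers had a median of -0.87 (camera adjusted p = 6.79e-05; adjusted p = 0.685 with an estimated correlation) and ependymal and choroid markers 1.59 (camera adjusted p = 0.00258; adjusted p = 0.17 with an estimated correlation). In all, 2755 of 21647 genes differed, 1338 up and 1417 down (edgeR).

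For APOE44 against APOE33, 64 of 21647 genes differed in effect between the cell types, 33 up and 31 down (edgeR), against 2463 at an unadjusted p under 0.05. Without the 5 libraries highest in markers of other cell types, an alternative added after the data were seen, it was 96, with 77 up, 19 down and 40 shared with the 64. The number was 403 (303 up, 100 down) without microglia APOE33 replicate 2, 40 without replicate 3, 41 without microglia APOE44 replicate 1 and 126 without replicate 5. Ncapg2 had the smallest adjusted p, with a difference of -2.87 (SE 0.12, adjusted p = 1.09e-15). It fell in APOE44 microglia and stood at 0.22 in astrocytes (adjusted p = 0.36). Ica1, an islet autoantigen gene, differed by 3.64 (SE 0.31, adjusted p = 2.92e-08) and Plxnd1 by 1.32 (SE 0.13, adjusted p = 3.88e-07). No member of a called list passed on its own. Oligodendrocyte lineage markers had a median of 0.92 (camera adjusted p = 0.00173), reactive astrocyte genes 0.41 (camera adjusted p = 0.00173) and collagens and matrix glycoproteins 0.43 (camera adjusted p = 0.00274). At an unadjusted p under 0.05 these had 1, 6 and 7 genes, and DESeq2 called 1, 0 and 1. Each of the 3 had adjusted p = 0.899 with an estimated correlation. Interferon genes (median 0.38, camera adjusted p = 0.0072), cell cycle genes (median 0.19, camera adjusted p = 0.0182) and neighbours of Apoe (median -0.08, camera adjusted p = 0.0212) had the same adjusted p = 0.899 with an estimated correlation. They had 1, 1 and 10 genes at an unadjusted p under 0.05, and DESeq2 called 0, 0 and 3. The interferon call was lost without astrocyte APOE33 replicate 1 or 2, APOE44 replicate 4, or microglia APOE33 replicate 6 or APOE44 replicate 1 or 6 (camera adjusted p from 0.055 to 0.43). The cell cycle call was lost without astrocyte APOE33 replicate 2 or APOE44 replicate 4, or microglia APOE33 replicate 6 or APOE44 replicate 5 or 6, with a camera adjusted p of 0.0613 or more. The call of the neighbours was lost without astrocyte APOE33 replicate 2 or 3, APOE44 replicate 1 or 4, or microglia APOE33 replicate 3 (camera adjusted p from 0.0511 to 0.135).

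Across all tested genes, the APOE44 and knock-out effects, which share the APOE33 libraries, correlated at 0.121 in astrocytes and 0.156 in microglia. Genes are not independent replicates, and 20 simulations of unchanged groups that shared simulated APOE33 libraries gave 0.451 and 0.448. The simulations held no changed genes, unlike the knock-out, so these values are not like for like. With the APOE33 libraries split by odd and even number, so that the effects shared none, the correlations were -0.062 and -0.0288 in astrocytes. In microglia they were -0.144 and 0.0694. In astrocytes 34 genes rose in both comparisons, 14 fell in both and 17 went opposite ways. In microglia these numbers were 29, 21 and 17. Shared APOE33 libraries by themselves favour calls in the same direction, and no expected overlap under shared controls was computed. Wdfy1 stood at 18.1 ± 0.415 CPM in knock-out astrocytes (SD, n = 4), near the 15.0 CPM of APOE44. Lrmda stood at 19.5 ± 0.503 CPM in knock-out (SD, n = 4), 16.1 ± 0.571 CPM in APOE44 and 1.83 ± 0.316 CPM in APOE33 microglia (SD, n = 6 each).

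**Figure D4:**
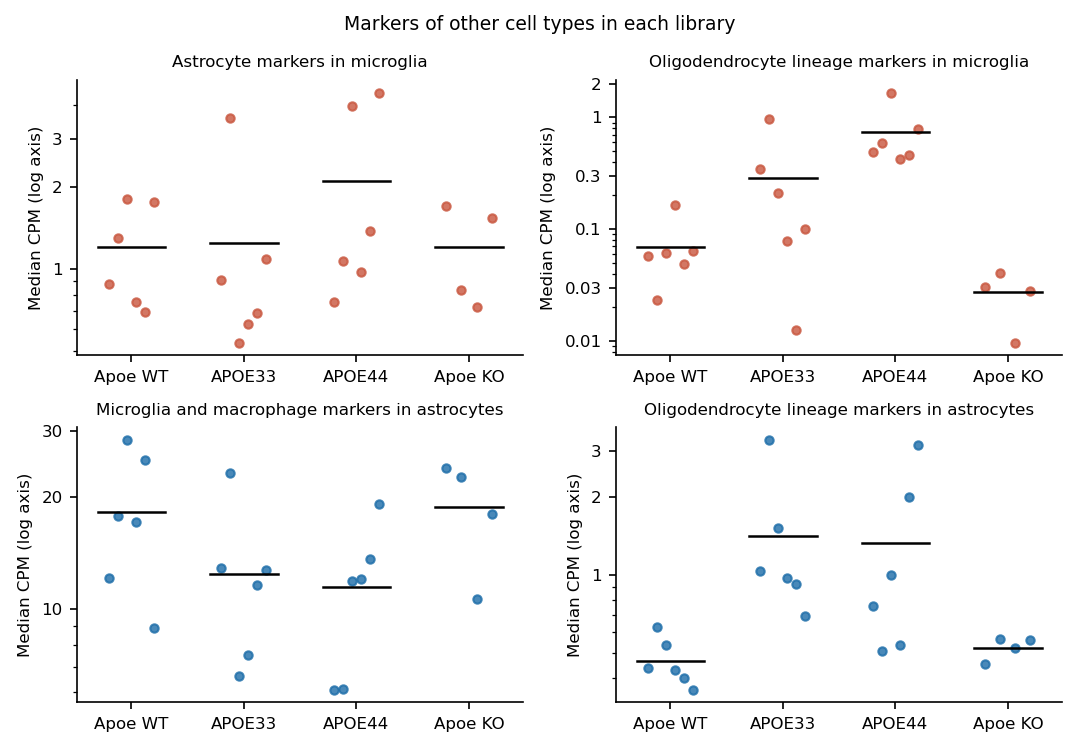
Median CPM of marker genes of other cell types (vertical log axis) in each library by genotype, with points for libraries and lines for group means. In microglia, the oligodendrocyte lineage markers average 0.739 CPM in APOE44 and 0.286 CPM in APOE33, and the astrocyte markers reach 4.43 CPM in APOE44 replicate 6.

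Every comparison with wild type is also one of batch 1 with batch 2. In knock-out astrocytes against wild type, 17 of 20 cholesterol biosynthesis enzymes were lower and 0 higher (median -0.55, camera adjusted p = 2.59e-12; adjusted p = 0.249 with an estimated correlation). Idi1, the isopentenyl isomerase, was lower by -1.25 (SE 0.097, adjusted p = 6.61e-09). Of 29 lysosomal genes 18 were higher (median 0.32, camera adjusted p = 7.56e-07; adjusted p = 0.249 with an estimated correlation), with the protease genes Ctsb at 1.05 (SE 0.12, adjusted p = 1.54e-06) and Ctsd at 0.77 (SE 0.11, adjusted p = 1.93e-05). APOE33 astrocytes had 13 of 20 of the enzymes lower (median -0.24, camera adjusted p = 0.000456; adjusted p = 0.538 with an estimated correlation), with Idi1 at -0.69 (SE 0.082, adjusted p = 1.17e-06). In them 17 of 29 lysosomal genes were higher (median 0.16, camera adjusted p = 0.000394; adjusted p = 0.538 with an estimated correlation). Of 18 astrocyte markers, 11 were lower and 3 higher in the knock-out (median -0.49, camera adjusted p = 0.00556; adjusted p = 0.574 with an estimated correlation), with the glutamine synthetase gene Glul at -1.05 (SE 0.078, adjusted p = 4.15e-09). The astrocyte markers were also called lower in APOE33 (camera adjusted p = 0.0348), but not without APOE33 replicate 2 or 5 (camera adjusted p = 0.0712 and 0.0584). Markers of other cells moved too. In the knock-out, ependymal and choroid markers were called lower (camera adjusted p = 0.00919), but not without knock-out replicate 1 (camera adjusted p = 0.0654). Neither of these calls held with an estimated correlation. In APOE33 astrocytes 10 of 10 border macrophage markers were lower (median -1.96, camera adjusted p = 1.38e-05; adjusted p = 0.497 with an estimated correlation), and in the knock-out 6 of 10 (median -1.43, camera adjusted p = 0.0139; adjusted p = 0.594 with an estimated correlation). Oligodendrocyte lineage markers were higher in 13 of 17 in APOE33 astrocytes (median 0.98, camera adjusted p = 0.000481; adjusted p = 0.538 with an estimated correlation). Of 44 measured neighbours of Apoe, 22 were higher and 9 lower in APOE33 astrocytes (camera adjusted p = 0.011; adjusted p = 0.538 with an estimated correlation). This list is the only 1 of 91 called whose median (0.15) and camera direction (up) differ in sign from its mean (-0.03). In all, 8155 of 21287 genes changed in the knock-out (4128 up, 4027 down) and 8312 in APOE33 (4285 up, 4027 down) (edgeR). With an absolute log2 fold change of at least 1 as well, 615 were up and 1498 down in the knock-out, and 347 up and 1139 down in APOE33.

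In knock-out microglia against wild type, 20 of 20 cholesterol biosynthesis enzymes were higher (median 1.14, camera adjusted p = 1.37e-09; adjusted p = 0.309 with an estimated correlation), with Tm7sf2 at 1.73 (SE 0.11, adjusted p = 1.73e-10). In APOE33 microglia Tm7sf2 alone was higher (0.52, SE 0.097, adjusted p = 0.000159), or 2 enzymes without APOE33 replicate 2, and the list was not called (median -0.24, camera adjusted p = 0.525). Antigen presentation genes were higher in 16 of 22 in the knock-out (median 0.40, camera adjusted p = 4.26e-07; adjusted p = 0.309 with an estimated correlation). In APOE33 they were higher in 15 of 22 (median 0.24, camera adjusted p = 0.000546; adjusted p = 0.541 with an estimated correlation). Cd74, the MHC class II invariant chain, was higher by 2.42 (SE 0.20, adjusted p = 2.29e-08) and 3.03 (SE 0.19, adjusted p = 7.04e-10). Type I interferon genes were higher in 17 of 36 in the knock-out, or 11 and 10 without knock-out replicates 2 and 3 (median 0.55, camera adjusted p = 0.000629; adjusted p = 0.723 with an estimated correlation). In APOE33 it was 13 of 36 (median 0.47, camera adjusted p = 0.00537; adjusted p = 0.847 with an estimated correlation). Homeostatic genes were higher in 16 of 21 in APOE33 (median 0.65, camera adjusted p = 1.15e-07; adjusted p = 0.333 with an estimated correlation), with Tmem119 at 2.13 (SE 0.15, adjusted p = 2.28e-09). In the knock-out they were higher in 9 of 21 and the list was not called (camera adjusted p = 0.136). Chemokines, cytokines and growth factors were higher in 22 of 41 and lower in 4 in APOE33 (median 0.62, camera adjusted p = 0.000402; adjusted p = 0.333 with an estimated correlation). In the knock-out 9 were higher and 6 lower, and the list was not called (camera adjusted p = 0.443). Beside them, microglia and macrophage markers were higher in 15 of 18 in APOE33 (median 0.55, camera adjusted p = 1.15e-07; adjusted p = 0.333 with an estimated correlation). Higher levels of these markers were not limited to APOE33. They stood at 1298 ± 101 CPM in APOE33 (SD, n = 6), 1308 ± 114 CPM in the knock-out (SD, n = 4) and 1098 ± 56.7 CPM in wild type (SD, n = 6). Oligodendrocyte lineage markers were higher in 9 of 16 in APOE33 (median 2.21, camera adjusted p = 0.00625; adjusted p = 0.739 with an estimated correlation). Mural and meningeal fibroblast markers were lower in 8 of 14 in the knock-out (median -1.28, camera adjusted p = 0.00511; adjusted p = 0.309 with an estimated correlation). In APOE33 7 of 14 were lower (median -0.75, camera adjusted p = 0.0046; adjusted p = 0.333 with an estimated correlation). In all, 7671 of 18079 genes changed in the knock-out (3786 up, 3885 down) and 8103 in APOE33 (4017 up, 4086 down) (edgeR). Of these, 586 were up and 1370 down by an absolute log2 fold change of at least 1 in the knock-out, and 588 up and 1401 down in APOE33.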

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

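Of the tests in this part, the 7 that weigh explanations were chosen only after the result was seen, and the counts over other splits of the libraries were planned.

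Microglia APOE33 replicate 2 lay far above the other 5 APOE33 microglia libraries in 3 marker groups. Its median CPM was 3.58 for astrocyte markers (others 0.536 to 1.09), 0.971 for oligodendrocyte lineage markers (others 0.0124 to 0.342) and 0.176 for neuron markers (others 0.0182 to 0.0674). Astrocyte APOE33 replicate 2 stood out in oligodendrocyte lineage markers, at 3.33 (others 0.695 to 1.52), and in neuron markers, at 0.508 (others 0.188 to 0.247). Oligodendrocyte lineage markers also set apart microglia APOE44 replicate 3, at 1.67 (others 0.428 to 0.793), and microglia wild-type replicate 4, at 0.163 (others 0.0232 to 0.0631). Border macrophage markers reached 4.37 in microglia APOE44 replicate 6 (others 1.96 to 2.86). Microglia and macrophage markers reached 1490 in microglia APOE33 replicate 3 (others 1220 to 1320). These are 9 of 88 groups tested, and chance alone gives about 4.4, or 1 in 20. APOE33 replicate 2 stands out in oligodendrocyte lineage and neuron markers in both cell types. No library was removed for it.

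Several genes had an APOE44 effect that differed between the cell types in the interaction test over the 32 libraries of batch 1, given here as microglia minus astrocytes. Ncapg2 differed by -2.871 (SE 0.118, adjusted p = 1.09e-15) and Ica1 by 3.64 (SE 0.306, adjusted p = 2.92e-08). St7, a gene named as a suppressor of tumorigenicity, differed by 1.36 (SE 0.118, adjusted p = 4.25e-08). Eps8l1 differed by 3.704 (SE 0.356, adjusted p = 2.98e-07), having risen in both cell types. Plxnd1 differed by 1.32 (SE 0.13, adjusted p = 3.88e-07) and Lgi4, a secreted protein of glia, by 3.234 (SE 0.354, adjusted p = 3.29e-06). The membrane protein gene Myadm differed by 0.8474 (SE 0.0945, adjusted p = 4.03e-06) and the imprinted gene Peg10 by 2.472 (SE 0.322, adjusted p = 0.000102). In all, 64 genes differed, and 6 of 60 splits of the libraries gave as many, the highest of the others 339. Chance is therefore not excluded for this number. That split calls several times the real count, which points to a structure of the samples. It follows neither genotype nor the class of even low counts (4 and 2 such libraries on its sides). One side holds microglia APOE33 replicate 2 and APOE44 replicates 3 and 6, the microglia libraries highest in astrocyte markers (3.58, 3.94 and 4.43 CPM). Astrocyte APOE33 replicate 2, high in oligodendrocyte lineage markers (3.33 CPM), is on that side, but astrocyte APOE44 replicate 6 (3.19 CPM) is not. Whether such markers account for the split was not tested.

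For the knock-out effect, Myadm differed by 1.91 (SE 0.112, adjusted p = 9.47e-12), with -0.862 in astrocytes and 1.05 in microglia. The kinase genes Map3k5 and Dmpk differed by -1.275 (SE 0.105, adjusted p = 1.32e-08) and -3.26 (SE 0.262, adjusted p = 1.32e-08), each up in knock-out astrocytes and down in knock-out microglia. Asap3, an ARF regulator, did so too and differed by -1.336 (SE 0.136, adjusted p = 4.71e-07). Hivep2, a zinc finger transcription factor, differed by -1.4 (SE 0.133, adjusted p = 2.5e-07). Mvd differed by 2.06 (SE 0.204), Mgst1 by 1.509 (SE 0.153) and Smpdl3a by 1.257 (SE 0.128), each with adjusted p = 4.71e-07. Of the gene lists, the cholesterol biosynthesis enzymes differed by a median of 1.837, with 20 of 20 higher. Fatty acid synthesis and lipid droplet genes differed by a median of 0.3864, with 9 of 22 higher and 13 not passing. Over all genes 2755 differed, and only the real split, 1 of 60, gave as many, the highest of the others 1485. A structure of the libraries that lines up with genotype by chance is not excluded by this. The split with 1485 keeps the 4 knock-out microglia libraries on one side and the 6 APOE33 microglia libraries on the other.

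Cholesterol biosynthesis enzymes went down in knock-out astrocytes and up in knock-out microglia. Scaling by 1 factor per library moves all genes alike. The list median lay apart from that of the other tested genes by -0.36 in astrocytes (SD of the members 0.203) and 1.52 in microglia (SD 0.437). TMM centres the other genes (median 0.00267 and -0.0203) and the list was picked for its shift. The test could thus hardly come out otherwise and adds nothing to the shift itself. The enzymes had a median level of 22.9 ± 0.499 CPM in knock-out astrocytes and 53.8 ± 5.03 CPM in knock-out microglia (SD, n = 4 each). Mixing of the cell types would therefore work against both changes, and the marker levels add little to that. Astrocytes mixed into the knock-out microglia are argued against by their markers, which had a median of 0.305 beside 1.5 for the enzymes. Microglia mixed into the knock-out astrocytes are argued against as well, with microglia markers at 1.82% of the knock-out microglia level in the highest library, 0.811% in the lowest and a mean of 0.957% in APOE33. The astrocyte fall is not particular to the knock-out, since APOE44 astrocytes had the enzymes at 22.3 ± 0.964 CPM against 25.3 ± 1.32 CPM in APOE33 (SD, n = 6 each). Both falls are measured against the same APOE33 libraries. An opposite response of the cell types to the loss of apolipoprotein E may remain as a hypothesis, found and examined on the same data, beside differences between the lines that were not tested.

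Only the real split, 1 of 100, gave as many genes as the knock-out against APOE33 in either cell type. In astrocytes the number was 3522 and the highest of the others 1607. In microglia it was 3899 and the highest of the others 2329. No other split drawn reached either number, but libraries with a structure of their own can line up with genotype by chance. Chance of that kind is not excluded. In either cell type, the split with the highest other number keeps all 4 knock-out libraries together and joins APOE33 replicates 4 and 5 to them. For microglia against astrocytes only the real split, 1 of 60, gave as many, with 18643 genes and 15017 as the highest of the others.

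The genes changed in APOE44 lay close together on the chromosomes. Without the libraries highest in markers of other cell types, the log2 values kept a median ratio of 0.986 in astrocytes and 1.01 in microglia. This argues against cells of another type in some libraries as the whole cause, though the genes were called with those libraries in. For that reason it carries little weight that 144 of 144 called genes kept their direction in each. Without those libraries, 92 genes were called in astrocytes (84 shared with the 144) and 106 in microglia (87 shared), with fewer samples. DNA of another mouse strain carried along in one of the lines is a candidate explanation, under which calls with a neighbour should more often move the same way in the other cell type (unadjusted p under 0.05). Of astrocyte calls, 55.3% with another call within 1 Mb did so (26 of 47) and 22.6% without one (14 of 62; Fisher's exact test, p = 0.000615), and of microglia calls 46.8% (22 of 47) and 24.7% (19 of 77; p = 0.0176). Calls near each other are not independent, and the labels do not say whether both cell types come from the same animals, so these p values overstate the evidence. Neighbours that share regulation could give the same, sequence variants were not examined, and an effect of APOE4 itself stays open and untested.

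The number of 144 genes changed by APOE44 in astrocytes was reached by 2 of 100 splits, the real one included. That share cannot exclude chance here, since libraries with a structure of their own can line up with genotype by chance. The other split called 386 genes, several times the real number, which points to a structure of the samples. It puts all 5 astrocyte libraries with a high share of even low counts on one side and 0 on the other. With that class as a covariate, added after the data were seen, 158 genes were called, 134 of them shared with the 144. In microglia, 144 was likewise reached by 2 of 100 splits, the real one included, with the same limit. The other split called 281 genes and has APOE33 replicates 4, 5 and 6 with APOE44 replicates 1, 3 and 6 on one side. It does not follow the class of even low counts, with 0 and 1 such libraries on its sides. Those APOE44 replicates had interferon genes at a median of 29.1, 26.3 and 31.1 CPM, against 16.7, 14.3 and 9.39 CPM in APOE44 replicates 2, 4 and 5. The APOE33 replicates on its sides overlap in these genes (17.7, 16.5 and 5.8 against 15.7, 18.5 and 8.78 CPM). In both cell types the other split parts APOE33 replicates 4, 5 and 6 from 1, 2 and 3, while the APOE44 replicates are parted differently. In microglia these APOE33 libraries differ in homeostatic genes (238 to 252 against 414 to 490 CPM). By chi-square per gene, replicates 4, 5 and 6 lie at 24.22 to 33.73 from each other, and 1 and 2 at 28.03. Between 1 and 2 on one hand and 4, 5 and 6 on the other it is 51.77 to 106.3. Replicate 3 lies far from all, at 92.8 and 123.9 from 1 and 2 and at 146.5 to 167.8 from 4, 5 and 6. Its share of even low counts, 78.7%, is the highest of all libraries. The labels do not say what sets these libraries apart.

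Comparisons with wild type called the most genes of those within a cell type, and batch cannot be told apart from genotype in them. Of the knock-out calls, 59.3% in astrocytes and 64.7% in microglia were called in the same direction in APOE33, where independent lists give 19.5% and 22.4%. A batch difference, the lines' shared background or the shared absence of mouse Apoe may each give such sharing, and the shared wild-type libraries add to it. Within 5 Mb of Apoe, 54.9% of genes in knock-out and 59.4% in APOE33 astrocytes were called, against 38.1% and 38.8% of other genes (Fisher's exact test, adjusted p = 0.00042 and 1.39e-05). In microglia it was 52.1% and 58%, against 42.4% and 44.6% (adjusted p = 0.0787 and 0.0106). Genes so close are not independent, the other genes were not matched for expression, and the cause of this local excess was not tested. Apoe and a few other genes taking many counts in wild type could shift the others only slightly. From the share of the 10 most abundant genes, all others could shift by at most 0.0676 on the log2 scale (APOE33 against wild-type microglia). Called genes had a median absolute log2 fold change of 0.396 in that comparison. Rounded to 3 digits, 100% of calls in each of the 4 comparisons lay beyond its own such shift. That share carries no weight, since a call rarely has so small a change and TMM removes a shift common to all genes. Only the real split, 1 of 100, gave as many genes in each of the 4 comparisons. This does not separate genotype from batch. In astrocytes the numbers were 8155 in the knock-out and 8312 in APOE33, with 2320 and 1163 as the highest of the others. In microglia they were 7671 and 8103, with 2516 and 3766.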

How the results depend on the processing

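Of the tests in this part, the fits without the libraries highest in markers of other cell types, without chromosomes 6, 7 and 12, and with the class of even low counts were chosen only after the result was seen. Over the alternatives tallied, 253 gene counts and medians around Apoe stayed close to the main value and 35 did not. Counts were held to 1.5 times, and medians to a typical standard error of genes on chromosome 7. Of named genes, 5737 values kept their side of the threshold, 205 lost and 25 gained a call, and 0 reversed with a call. Of lists, 1373 values did so, 127 lost and 49 gained a call. A changed sign without a call was not tallied. The gene tally holds only the lowest and highest leave-one-out value and the list tally none, and both omit, for example, the filter and RIN fits. Camera with an estimated correlation accounts for 89 of the lost list calls. The neighbours of Apoe in microglia against astrocytes reversed with fry (adjusted p = 0.0397, down; camera 0.656, up); the cause was not tested. For APOE44, the DESeq2 Wald test called 319 genes in astrocytes (136 shared with the 144), 418 in microglia (136 shared) and 381 for the difference between the cell types (61 shared with 64), where the stricter filter gave 100; the cause was not tested. With a replicate block, the counts were 70, 51 and 38 for these comparisons and 1892 for knock-out against APOE33 astrocytes; the cause was not tested. Whether numbers pair the libraries within a cell type stays open. Correlations of equal numbers passed 0.1 in 4 of 30 pairs within astrocytes (highest 0.167) and 4 of 30 within microglia (0.218). Across cell types, sex labels match in 22 of 22 pairs, which argues that equal numbers belong together. The correlations there were low, over 0.1 in 4 of 22 (median 0.0769, 7 best with their own). The tests between cell types treat libraries as independent. With the replicate block, 2169 genes differed for the knock-out between the cell types, 2018 of them shared with the 2755. Knock-out against APOE33 astrocytes gave 1760 with only those 10 libraries. An absolute log2 fold change of at least 1 left, by its construction, 56, 688, 2113 and 1486 genes in astrocytes (APOE44, knock-out against APOE33, knock-out and APOE33 against wild type), 43, 722, 1956 and 1989 in microglia, and 21 and 838 for the APOE44 and knock-out differences between the cell types. Without chromosomes 6, 7 and 12 fewer genes were counted, 75 in astrocytes and 85 in microglia for APOE44. Without the 2 astrocyte libraries highest in other markers it was 92 (84 shared), with fewer samples. Leaving out each library gave 85 to 126 (astrocytes) and 81 to 191 (microglia) for APOE44, 1836 to 3688 for knock-out against APOE33 astrocytes, and 40 to 403 for the APOE44 difference. The lowest and highest came without astrocyte APOE44 replicate 5 and APOE33 replicate 2, microglia APOE44 replicates 4 and 5, astrocyte knock-out replicate 1 and APOE33 replicate 5, and microglia APOE33 replicates 3 and 2. Simulated changes that were missed had higher dispersions than those called, and depth was not varied.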

Other observations

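Both gene lists of this part were chosen only after the result was seen, and so were these tests and the genes named. Of 16 immediate early genes, which respond quickly to stimulation, 7 fell and 0 rose in knock-out against APOE33 astrocytes, with a median log2 value of -1.82 (camera p = 1.16e-07; p = 0.101 with an estimated correlation). In knock-out microglia, the libraries in which some chemokines fell, 8 fell and 0 rose, with a median of -0.904 (camera p = 1.75e-05; p = 0.117 with an estimated correlation). Of 13 mitochondrially encoded proteins, 7 rose and 0 fell in APOE44 microglia, with a median of 0.405 (camera p = 6.02e-08; p = 0.0063 with an estimated correlation). The respiratory chain gene mt-Nd1 rose by 0.4845 (SE 0.0724, n = 6 and 6, edgeR adjusted p = 0.00226), while 6 of the 13 had negative values. The share of all counts from mitochondrial genes was 1.604 ± 0.0717% in APOE44 and 1.23 ± 0.188% in APOE33 microglia (SD, n = 6 each), with ranges of 1.5 to 1.72 and 0.906 to 1.387, and it was not adjusted for in the tests. The same list had a median of -0.061 in APOE44 astrocytes and was not called there.

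Wdfy1 had similar levels in wild-type and APOE33 cells, at 76.1 and 73.8 CPM in astrocytes and 55.3 and 56.3 CPM in microglia. In APOE44 and knock-out cells it stood at 15 and 18.1 CPM in astrocytes and 14.7 and 12.6 CPM in microglia. Eps8l1 was low in APOE33 alone, at 0.699 CPM in astrocytes and 0.0441 CPM in microglia. In wild type, APOE44 and knock-out it stood at 7.81, 11.7 and 7.34 CPM in astrocytes, and at 4.99, 9.29 and 3.27 CPM in microglia. In 12 of the 44 libraries, 5 of astrocytes and 7 of microglia, more than 70% of the counts from 1 to 9 were even. The microglia libraries among them are APOE33 replicate 3 (78.7%) and every wild-type library (70.1% to 72.6%). In microglia this class therefore nearly coincides with wild type, and it was not adjusted for in those comparisons.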
